A study of Homo sapiens with 9 samples.

How the data were processed

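RNA was sequenced from U2OS cells in 3 groups of 3 libraries, named WT, A1-2A and A-KO by the genotype that the labels give. Per the labels, cells were at passages 15 to 18, and libraries were made from 1000 ng of total RNA each with the TruSeqV2 kit. The submitters' processing notes name STAR and RSEM without a version or a role. The genome build and annotation are not given in the sources used here, and neither is the strandedness of counting, so reads from overlapping genes may be shared. The authors deposited 2 tables of 57773 genes, 1 per mutant, each with a TPM column for every library of that mutant and of WT. As deposited, each TPM column was scaled by the authors to the same total with values to 2 decimals, so the depth of a library and whole reads cannot be recovered. The WT columns are identical in both tables. The deposited tables also hold a p-value per gene and the same adjusted by Benjamini-Hochberg, which the authors made with an equal-variance test on TPM values. Recomputing that test from the TPM columns gave the deposited p-values with a largest difference of 5.0e-08. At a deposited adjusted p-value under 0.05 stood 6634 of 21174 genes with a p-value for A1-2A (4632 higher, 2002 lower) and 3746 of 21352 for A-KO (1912 higher, 1834 lower). Those p-values were not used further.

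TPM values were transformed to log2(TPM + 1). Genes with at least 1 TPM in at least 3 libraries of a fit were kept. Entries sharing a symbol were kept apart, numbered in the order of their values. Each mutant was compared with WT over the 6 libraries of its table. The mutants were compared with each other in a fit of all 9 libraries. The tables were joined by symbol, and entries sharing a symbol were matched by their WT values. Where those were the same, the match was ambiguous, and 2016 such entries, of which 1 passed the minimum, were left out of the join. Each gene was tested with limma (lmFit, eBayes with a variance trend, two-sided), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. A further count took genes with an absolute log2 fold change of at least 1 on the same scale. No term for a batch or replicate number was included, since the labels name no batch and do not pair the libraries. With 3 libraries per group, ranges that do not overlap arise by chance in 10% of genes, and an exact permutation test of one gene cannot go below 0.1.

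Gene lists were tested with camera in limma, with its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists with at least 5 genes tested. Of 34 lists, 33 reached that number. They were AMPK subunits, AMPK kinases and partners, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, mitochondrial biogenesis, oxidative phosphorylation, glycolysis and hypoxia, lysosome and autophagy, mTORC1 and translation, and ATF4 and unfolded protein response. Further lists were NRF2 antioxidant, FOXO and catalase (FOXO-related genes), p53 targets, G1/S and DNA replication, G2/M and mitosis, YAP and TEAD targets, extracellular matrix, osteoblast lineage, epithelial markers, mesenchymal transition and neuronal markers. The rest were interferon response, antigen presentation, NF-kB and inflammation, TGF-beta response, WNT response, immediate early, ribosomal proteins, mitochondrial genome, replication histones and nuclear RNA, cancer-testis antigens and housekeeping. Blood cell markers were the list not tested. A count adjusted over the list alone uses the p-values of its members only.

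Lists, tests, the alternatives not marked otherwise and the rule for naming genes were fixed before the data were examined. The rule named the AMPK subunits and, for each mutant against WT, the 10 largest rises and 10 largest falls among genes past the threshold. Those genes had groups of libraries that did not overlap and a mean of at least 5 TPM in the higher group. For the mutants against each other it took 5 in each direction. It left out clone identifiers (names with AC, AL, AP, RP or CT before a number or hyphen), LINC genes, pseudogenes and sex-linked genes of the Y chromosome and X inactivation. Applied to the letter, it passed over CT45 genes, whose names start with CT and a number, and kept LA16c-360H6.2. From each list described it took up to 4 members with the smallest adjusted p, at least 1 in each direction where both had one. Gene coordinates are those of the deposited tables.

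The alternatives tried were pseudocounts of 0.1 and 0.5, no filter, a minimum of 5 TPM, rescaling by median ratios over genes above 1 TPM, no variance trend, the replicate number as a block, and all 9 libraries or only 6 in a fit. Each replicate was also left out in turn, and treat and fry from limma were run. Where 1 group was left with 2 libraries, the fit pooled the spread over groups. Genes reaching 1 TPM in that group alone then missed the minimum and were not tested. Protein-coding genes only, and a set without mitochondrial and ribosomal protein genes, were added later. The procedure was tested on simulated data with the spread of each comparison, where the share of false calls was 3.11% for A1-2A against WT, 4.08% for A-KO against WT and 5.71% for A1-2A against A-KO. There 100 genes were changed 2-fold and 100 were changed 1.5-fold, all with a mean log2(TPM + 1) of at least 2. Noise was drawn for each gene apart. The shares found do not describe weaker genes or data in which many genes change. Transcript lengths, GC content and gene types came from GENCODE 29, joined by symbol. Length and GC content were those of the longest transcript of each symbol. The tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.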

Results

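RNA levels were measured by RNA-seq in U2OS, an established human osteosarcoma cell line, to look at transcription downstream of AMPK, the kinase that senses a falling cellular energy charge. The 9 libraries fell into 3 groups of 3: wild-type cells (WT), cells labelled AMPKα-KO (A-KO) and cells labelled AMPKα1-2A (A1-2A). The labels do not say how either mutant line was made or in which background A1-2A was placed. Nothing in them says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries. The values were given as TPM, a unit that scales every library to the same total and keeps no depth, so the depth is unknown. Between 15125 and 15629 genes per library stood at 1 TPM or more. Correlations of log2(TPM + 1) ran from 0.985 to 0.990 between libraries of one group and from 0.960 to 0.973 between groups. In a principal component analysis over 16091 genes, the first component held 41.5% of the variance and parted WT from both mutants. The second component held 26.3% and parted A1-2A from A-KO.

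The targeted genes came first. PRKAA1 encodes the catalytic α1 subunit of AMPK (chromosome 5, 40759481 to 40798476 in the deposited coordinates, whose genome build is not given in the sources used here). It stood at 38.89, 30.24 and 27.08 TPM in the WT libraries and at 27.31, 41.02 and 33.17 TPM in A-KO. That difference was smaller than the spread between libraries (log2 fold change 0.072, SE 0.16, adjusted p = 0.757). In A1-2A it stood at 233.73, 241.22 and 228.87 TPM, 7.32 times the WT mean (log2 fold change 2.85, SE 0.11, adjusted p = 1.15e-06), and it was likewise above A-KO (2.78, adjusted p = 1.52e-06). PRKAA2, which encodes the other catalytic subunit, was low in every library, at 1.67, 1.46 and 1.49 TPM in WT, 1.46, 1.26 and 1.26 TPM in A1-2A and 0.78, 1.32 and 1.16 TPM in A-KO. It did not pass against WT in A1-2A (adjusted p = 0.467) or in A-KO (0.193). An edit can remove a protein without lowering its mRNA, so these gene-level values neither bear out nor contradict the A-KO label.

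Both regulatory β subunit genes were higher in both mutants. PRKAB2 went from 15.4 ± 1.31 TPM in WT (mean ± SD, n = 3 throughout) to 26.2 ± 1.77 in A1-2A (log2 fold change 0.73, adjusted p = 0.000169) and 20.4 ± 1.43 in A-KO (0.39, adjusted p = 0.0122). The A-KO call was lost without WT replicate 2 (adjusted p = 0.0503, range over the alternatives 0.00465 to 0.0503). PRKAB1 went from 16.2 ± 0.978 TPM to 20.96 ± 1.49 in A1-2A (0.35, adjusted p = 0.00550) and 25.6 ± 0.490 in A-KO (0.63, adjusted p = 0.000439). Its A1-2A call was lost after rescaling each library by its median ratio to the others (0.21, adjusted p = 0.0697, range 0.00282 to 0.0697). Among the γ subunit genes, PRKAG1 (62.1 ± 6.78 TPM in WT) had an adjusted p of 0.962 in A1-2A and 0.0771 in A-KO, where it passed only without WT replicate 1 (0.0465, range 0.0465 to 0.245). PRKAG2 (4.68 ± 0.471 TPM in WT) had an adjusted p of 0.125 in A-KO. In A1-2A it lay at the threshold (log2 fold change 0.32, adjusted p = 0.0502) and passed under some alternatives, such as without WT replicate 1 (0.0302) or A1-2A replicate 3 (0.0393, range 0.0302 to 0.194). PRKAG3 was listed at 0 in all WT and A1-2A libraries and at 0.07, 0.16 and 0 TPM in A-KO. As a list, the 6 tested subunit genes had a median log2 fold change of 0.34 in A1-2A (camera adjusted p = 0.217) and 0.25 in A-KO (0.293). In A1-2A 3 were higher, and 4 adjusted over the list alone, against 2 and 2 in A-KO.

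**Figure D1:**
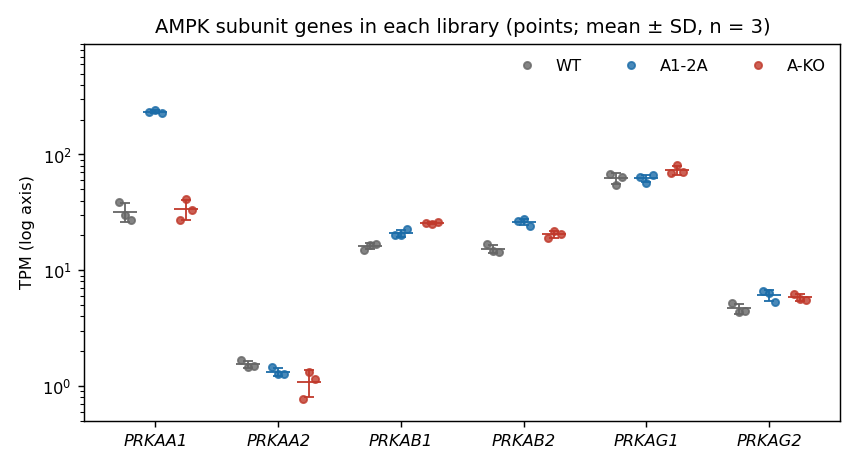
TPM (log axis) of the AMPK subunit genes above 0 in every library, with 1 point per library and the group mean ± SD (n = 3). PRKAA1 stood between 228.87 and 241.22 TPM in A1-2A and between 27.08 and 41.02 TPM in WT and A-KO.

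The comparison of A1-2A with WT asked which RNA levels went with the A1-2A line. The lists of mesenchymal transition, matrix, lipid synthesis and lysosome genes stood higher in A1-2A than other genes, and those of ribosomal protein, DNA replication and histone genes lower. None of these calls held with an estimated correlation (camera adjusted p = 0.387 to 0.512). HSPB7, a small heat shock protein gene of muscle (chromosome 1, 16340523 to 16346089), went from 0.643 ± 0.320 TPM in WT to 33.4 ± 1.97 in A1-2A. IGFBP4, a secreted binding protein of insulin-like growth factors (chromosome 17, 38599702 to 38613983), went from 44.8 ± 0.820 TPM to 0.0433 ± 0.0451. With limma, 8286 of the 15468 genes tested passed an adjusted p of 0.05, 5680 higher and 2606 lower (68.5% higher). Of these, 761 also differed at least 2-fold, 516 higher and 245 lower (67.8% higher). The median over all genes was shifted by 0.14 (log2), and rescaling each library by its median ratio moved it to -0.0057. The calls then split into 3939 higher and 4089 lower (49.1% higher), and at 2-fold into 331 and 352 (48.5% higher), so changes smaller than that shift have no fixed direction. On data simulated for 15468 genes, the test recovered 90% of 2-fold and 66% of 1.5-fold changes. None was planted in genes with a mean log2(TPM + 1) under 2.

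Among the genes that the naming rule admits, leaving aside HSPB2-C11orf52, the largest rises were HSPB7 (log2 fold change 4.40, SE 0.15, adjusted p = 5.81e-07), HERC3, an E3 ubiquitin ligase gene (log2 fold change 3.26, SE 0.19, adjusted p = 6.36e-06), and GTSF1, a gametocyte factor of the piRNA pathway (9.98 ± 0.511 to 104 ± 3.56 TPM, log2 fold change 3.26, SE 0.059, adjusted p = 2.25e-08). For the further genes, the number in parentheses is the log2 fold change on the log2(TPM + 1) scale, which understates changes of weakly expressed genes, and all of them passed an adjusted p of 0.05 unless stated. HSPB2, another small heat shock protein gene, went from 4.42 ± 1.00 to 40.9 ± 1.29 TPM (2.97). The read-through gene HSPB2-C11orf52 overlaps it, was listed at 0 in all WT libraries and stood at 8.03, 11.88 and 7.56 TPM in A1-2A, so how reads were split between the pair is uncertain. The striated muscle gene CSRP3 (2.91), PRKAA1, the inflammasome-related gene NLRP2 (2.80), the kinase-like gene MAP3K7CL (2.61) and the tripartite motif gene TRIM29 (2.61) were also among the 10 largest rises.

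IGFBP4 had the largest fall among the genes tested (log2 fold change -5.46, SE 0.095, adjusted p = 2.10e-08). GPAT2, a mitochondrial glycerol-3-phosphate acyltransferase gene, went from 23.5 ± 1.19 TPM to 0.14, 0.24 and 0 in the A1-2A libraries (log2 fold change -4.44, SE 0.12, adjusted p = 3.09e-07). The annexin gene ANXA10 (-3.55), the interferon-induced gene IFI44 (-3.19), the transglutaminase gene TGM2 (-2.83) and the homeobox gene HOXB2 (-2.53) fell too. So did SERPINF1 (-2.57), which encodes pigment epithelium-derived factor. The apolipoprotein gene APOC1 stood at 8.34, 7.24 and 8.45 TPM in WT and was listed at 0 in all A1-2A libraries. MAGEA2 (-2.996) and HIST2H4B (-2.51) have near-identical copies, so their values are uncertain, and HIST2H4B stood at 12.1, 3.28 and 2.49 TPM in the WT libraries.

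Lipid synthesis genes stood higher in A1-2A. For cholesterol synthesis, 18 of 24 tested members were higher and 3 lower (18 and 3 adjusted over the list alone). The median was 0.51, and 0.35 after rescaling (camera adjusted p = 0.00113, and adjusted p = 0.400 with an estimated correlation). The camera test compares a list with all other genes tested, and none of the 33 lists fixed beforehand passed it in any comparison with an estimated correlation. SREBF2 (1.16), the transcription factor gene that controls the pathway, the squalene epoxidase gene SQLE (0.91) and MSMO1 (0.76) rose, while the sterol isomerase gene EBP (-0.22) fell. In fatty acid synthesis, 11 of 17 tested members were higher and 2 lower (11 and 2 adjusted over the list alone). The median was 0.42, and 0.26 after rescaling (camera adjusted p = 0.0346, and adjusted p = 0.506 with an estimated correlation). The elongase gene ELOVL5 (0.81), the fatty acid synthase gene FASN (0.38) and the desaturase gene SCD (0.57) rose and ELOVL6 (-0.60) fell. That list missed the threshold at a minimum of 5 TPM (adjusted p = 0.0682), without the variance trend (0.0519) and over protein-coding genes (0.0674), with a range of 0.00361 to 0.0682 over the alternatives.

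Among lysosome and autophagy genes, 27 of 33 tested members were higher and 1 lower (27 and 1 adjusted over the list alone). The median was 0.40, and 0.25 after rescaling (camera adjusted p = 5.35e-05, and adjusted p = 0.464 with an estimated correlation). The cathepsin gene CTSL (0.95), the lysosomal membrane gene LAMP2 (1.03) and the melanosome glycoprotein gene GPNMB (1.17) rose, while the autophagy gene WIPI2 (-0.39) fell. Among FOXO-related genes, 14 of 16 tested members were higher and 0 lower (14 and 0 adjusted over the list alone). The median was 0.46, and 0.32 after rescaling (camera adjusted p = 0.00869, and adjusted p = 0.506 with an estimated correlation). They included the transcription cofactor gene CITED2 (0.50), the PI3K inhibitor gene PIK3IP1 (1.18) and FOXO3 (0.76), with the superoxide dismutase gene SOD2 (0.48).

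The mesenchymal transition and extracellular matrix lists had the highest medians. Of the mesenchymal transition list, 14 of 20 tested members were higher and 2 lower (14 and 2 adjusted over the list alone). The median was 0.71, and 0.56 after rescaling (camera adjusted p = 0.000431, and adjusted p = 0.400 with an estimated correlation). Its risers included actin-binding genes of smooth muscle. TAGLN went from 133 ± 4.15 to 429 ± 7.69 TPM (log2 fold change 1.68, SE 0.036, adjusted p = 5.85e-08), CNN1 from 27.3 ± 1.89 to 154 ± 1.08 TPM (log2 fold change 2.46, SE 0.055, adjusted p = 6.49e-08), and CALD1 (1.57) rose with them, whereas the N-cadherin gene CDH2 (-0.39) fell. Of the extracellular matrix list, 21 of 26 tested members were higher and 3 lower (21 and 3 adjusted over the list alone). The median was 0.68, and 0.53 after rescaling (camera adjusted p = 0.000185, and adjusted p = 0.512 with an estimated correlation). Fibronectin FN1 (0.93), the protease inhibitor gene TIMP3 (1.10) and the collagen gene COL5A1 (1.11) rose and COL6A1 (-1.08) fell. In the TGF-beta response, 13 of 20 tested members were higher and 2 lower (14 and 2 adjusted over the list alone). The median was 0.29, and 0.14 after rescaling (camera adjusted p = 0.0264, and adjusted p = 0.512 with an estimated correlation). The ligand gene TGFB2 (1.23) and PMEPA1 (1.07) rose, and the matrix gene TGFBI (-1.15) fell. The list missed the threshold at a minimum of 5 TPM (adjusted p = 0.0682) and over protein-coding genes (0.0589), with a range of 0.000411 to 0.0682. For YAP and TEAD targets, 15 of 24 tested members were higher and 2 lower (15 and 3 adjusted over the list alone). The median was 0.30, and 0.14 after rescaling (camera adjusted p = 0.0367, and adjusted p = 0.512 with an estimated correlation). TEAD1 (0.88) and ANKRD1 (0.42) rose and CYR61 (-0.58) fell. The call was lost after rescaling (adjusted p = 0.0690), without WT replicate 3 (0.0792) and under 5 other settings, with a range of 0.00220 to 0.0792.

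Ribosomal protein genes had the smallest adjusted p of the falling lists, and 35 of 39 tested members were lower and 2 higher (35 and 2 adjusted over the list alone). The median was -0.30 and, after rescaling, -0.45 (camera adjusted p = 1.95e-18, and adjusted p = 0.400 with an estimated correlation). RPL5 (-0.74) and RPS2 (-0.68) fell. A rise of RPL7 (0.25) was lost after rescaling (adjusted p = 0.167, range 0.000109 to 0.167). Ribosomal protein genes took 17.5% to 17.8% of all TPM in the A1-2A libraries and 20.8% to 22.3% in WT. For DNA replication genes, 15 of 30 tested members were lower and 1 higher (15 and 1 adjusted over the list alone). The median was -0.13, and -0.29 after rescaling (camera adjusted p = 1.05e-06, and adjusted p = 0.387 with an estimated correlation). The nucleotide synthesis genes TYMS (-0.63) and TK1 (-0.64) and the helicase gene MCM7 (-0.51) fell and RRM2 (0.29) rose. For mitotic genes, 11 of 32 tested members were lower and 6 higher (11 and 6 adjusted over the list alone). The median was -0.034, and -0.19 after rescaling (camera adjusted p = 0.0489, and adjusted p = 0.584 with an estimated correlation). BIRC5 (-0.38) and PLK1 (-0.41) fell, and the spindle gene TPX2 (0.35) and the cytokinesis gene ANLN (0.46) rose. Without WT replicate 1 the median of the mitotic list turned to 0.030 (adjusted p = 0.155). The call was also lost without A1-2A replicate 2 (0.0672) or 3 (0.0732) and under 4 other settings, with a range of 0.00137 to 0.155. For oxidative phosphorylation, 13 of 35 tested members were lower and 4 higher (13 and 4 adjusted over the list alone). The median was -0.031, and -0.19 after rescaling (camera adjusted p = 0.00335, and adjusted p = 0.400 with an estimated correlation). The ATP synthase genes ATP5G1 (-0.78) and ATP5F1 (-0.57) and the succinate dehydrogenase gene SDHA (-0.80) fell and SDHC (0.29) rose.

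Replication histone and nuclear RNA genes, a list fixed as a sign of RNA quality and library selection, moved with the falling groups. Of them, 8 of 12 tested members were lower and 1 higher (8 and 2 adjusted over the list alone). The median was -0.75, and -0.90 after rescaling (camera adjusted p = 5.35e-05, and adjusted p = 0.387 with an estimated correlation). The linker histone gene HIST1H1C went from 209 ± 10.5 to 39.8 ± 0.412 TPM (log2 fold change -2.36, SE 0.047, adjusted p = 3.60e-08), HIST1H2AC (-2.12) and HIST1H2BK (-1.22) fell too, and the nuclear RNA MALAT1 (0.58) rose. In the interferon response, 9 of 19 tested members were lower and 2 higher (9 and 3 adjusted over the list alone). The median was -0.16, and -0.24 after rescaling (camera adjusted p = 0.0112, and adjusted p = 0.387 with an estimated correlation). IFI44, IFI6 (-0.90) and ISG15 (-0.66) fell and the signalling gene STAT2 (0.69) rose. That call was lost without any one WT library. Such fits also left out members at 1 TPM or more in WT alone, such as IFI44, as the minimum asks for 3 libraries. The median was -0.034 without WT replicate 1 (adjusted p = 0.0821), 0.042 without replicate 2 (0.132) and 0.044 without replicate 3 (0.103), with a range of 0.00220 to 0.132.

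Lists that did not pass in A1-2A follow with median log2 fold change and camera adjusted p: AMPK kinases and partners (0.33, 0.0801), fatty acid oxidation (-0.17, 0.106), ATF4 and unfolded protein response (0.26, 0.106), p53 targets (0.21, 0.149), osteoblast lineage (0.51, 0.235), epithelial markers (-0.31, 0.0814), neuronal markers (0.49, 0.306), NF-kB and inflammation (-0.26, 0.149), WNT response (0.23, 0.704), immediate early (0.26, 0.718). With no filter, AMPK kinases and partners (0.00220, range 0.00220 to 0.180), ATF4 and unfolded protein response (0.00361, range 0.00361 to 0.307) and p53 targets (0.0220, range 0.0220 to 0.318) passed. Epithelial markers passed with all 9 libraries in the fit (0.0363) and over protein-coding genes (0.0362, range 0.0362 to 0.446). Rescaling turned 7 further medians, none past the test, to the other sign: glycolysis and hypoxia (0.026, 0.494), mTORC1 and translation (0.041, 0.785), NRF2 antioxidant (0.097, 0.938), antigen presentation (0.14, 0.971), mitochondrial genome (0.12, 0.545), cancer-testis antigens (0.024, 0.718), housekeeping (0.0090, 0.718). The test pointed down where the median was positive for glycolysis, mTORC1, cancer-testis antigens and housekeeping. Mitochondrial biogenesis (-0.0071, 0.306) had a mean of 0.028, opposite in sign to its median. Blood cell markers had fewer than 5 genes above the minimum in every comparison and were not tested.

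The comparison of A-KO with WT asked which RNA levels went with the line labelled as lacking AMPKα. The list around the stress-response factor ATF4 stood higher in A-KO than other genes, with those of lysosome, FOXO-related and mesenchymal transition genes, and the glycolysis, cell cycle and cholesterol synthesis lists stood lower. With an estimated correlation these calls were lost (camera adjusted p = 0.465 to 0.704), and 13 of 24 cholesterol synthesis genes did not pass one by one. FGF21, a stress-induced hormone gene (chromosome 19, 49258816 to 49261587), went from 3.69 ± 0.537 TPM in WT to 124 ± 19.98 in A-KO. The inducible HSP70 gene HSPA1A went from 125 ± 7.16 to 19.6 ± 2.67 TPM. In limma, 6025 of 15561 genes passed an adjusted p of 0.05, 3325 higher and 2700 lower (55.2% higher, and 49.8% after rescaling). Of these, 737 also differed at least 2-fold, 445 higher and 292 lower. On data simulated for 15561 genes, the test recovered 88% of 2-fold and 53% of 1.5-fold changes, again planted outside the weaker genes.

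FGF21 had the largest rise that the naming rule admits (log2 fold change 4.73, SE 0.13, adjusted p = 4.85e-07). HSPB7 (log2 fold change 4.14, SE 0.16, adjusted p = 1.70e-06), GTSF1 (log2 fold change 3.27, SE 0.071, adjusted p = 6.37e-08), HSPB2 (3.18), TRIM29 (2.96) and CSRP3 (2.94) were among the 10 largest rises here as in A1-2A. HSPB2-C11orf52, listed at 0 in WT, stood at 10.7, 11.49 and 14.07 TPM. TSC22D3, a glucocorticoid- and FOXO-induced gene, went from 4.99 ± 0.829 to 53.1 ± 7.72 TPM (3.17). The microtubule-associated protein gene MAP2 (2.999) and TXNIP (2.76), which encodes a brake on glucose uptake, rose as well. The largest falls that the rule admits were IGFBP4 (log2 fold change -5.38, SE 0.11, adjusted p = 6.27e-08) and GPAT2 (log2 fold change -4.50, SE 0.14, adjusted p = 6.38e-07), and further falls were ANXA10 (-3.71), TGM2 (-3.20), IFI44 (-3.17), HOXB2 (-2.64) and SERPINF1 (-2.52). APOC1 was at 0, 0 and 0.56 TPM in the A-KO libraries (-2.95). MAGEA2 (-3.04) and HSPA1A (log2 fold change -2.62, SE 0.095, adjusted p = 1.64e-06) have near-identical copies that share their reads, so their values are uncertain.

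Of the ATF4 and unfolded protein response list, 21 of 27 tested members were higher and 0 lower (21 and 1 adjusted over the list alone). The median was 1.39 (camera adjusted p = 8.24e-12, and adjusted p = 0.465 with an estimated correlation). CHAC1, a glutathione-degrading enzyme gene, went from 12.6 ± 1.12 to 81.2 ± 4.47 TPM (log2 fold change 2.60, SE 0.083, adjusted p = 6.77e-07). DDIT3, which encodes the transcription factor CHOP, went from 21.1 ± 2.59 to 108 ± 2.10 TPM (2.31), and XBP1 from 60.4 ± 1.77 to 183 ± 11.8 TPM (1.58). Among FOXO-related genes, 9 of 16 tested members were higher and 0 lower (11 and 0 adjusted over the list alone). The median was 0.36 (camera adjusted p = 0.000544, and adjusted p = 0.495 with an estimated correlation). TXNIP, the growth arrest gene GADD45A (0.49), PIK3IP1 (1.74) and FOXO3 (1.05) rose. Among lysosome and autophagy genes, 17 of 33 tested members were higher and 2 lower (18 and 3 adjusted over the list alone). The median was 0.27 (camera adjusted p = 0.00618, and adjusted p = 0.704 with an estimated correlation). CTSL (0.94) and the autophagosome genes GABARAPL1 (1.10) and MAP1LC3B (1.25) rose, and the cathepsin gene CTSB (-0.33) fell. Of the mesenchymal transition list, 12 of 20 tested members were higher and 4 lower (12 and 4 adjusted over the list alone). The median was 0.29 (camera adjusted p = 0.00977, and adjusted p = 0.495 with an estimated correlation). It included TAGLN (1.32), CNN1 (1.97) and the myosin light chain gene MYL9 (1.13), and CDH2 (-0.76) fell.

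Among glycolysis and hypoxia genes, 18 of 28 tested members were lower and 3 higher (18 and 3 adjusted over the list alone). The median was -0.33 (camera adjusted p = 5.22e-05, and adjusted p = 0.465 with an estimated correlation). The enzyme genes ENO2 (-1.01) and TPI1 (-0.75) fell, GAPDH went from 9825 ± 327 to 5942 ± 285 TPM (-0.73), and the angiogenic factor gene VEGFA (1.88) rose. Low GAPDH was not particular to A-KO, as it stood at 5979.97, 5963.82 and 6052.82 TPM in A1-2A. TPI1 stood at 961.14, 953.94 and 969.02 TPM there, also below every WT library. In A1-2A against WT, 6 of the 28 tested members were lower and 10 higher. In cholesterol synthesis, 9 of 24 tested members were lower and 2 higher (10 and 2 adjusted over the list alone). The median was -0.16 (camera adjusted p = 0.00977, and adjusted p = 0.530 with an estimated correlation). HMGCS1 (-1.12) and FDFT1 (-0.83) fell and SREBF2 (0.57) rose. Of the mitotic genes, 18 of 32 tested members were lower and 0 higher (18 and 1 adjusted over the list alone). The median was -0.25 (camera adjusted p = 1.37e-05, and adjusted p = 0.495 with an estimated correlation). The mitotic kinase gene PLK1 (-0.93), the kinesin gene KIF20A (-0.75) and the cyclin genes CCNF (-0.70) and CCNB1 (-0.49) fell. Of the DNA replication genes, 14 of 30 tested members were lower and 2 higher (14 and 2 adjusted over the list alone). The median was -0.22 (camera adjusted p = 0.000113, and adjusted p = 0.468 with an estimated correlation). The helicase gene MCM4 (-0.57), the cyclin gene CCNA2 (-0.65) and TK1 (-0.47) fell and E2F1 (0.38) rose.

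Of the WNT response genes, 9 of 20 tested members were lower and 1 higher (12 and 1 adjusted over the list alone). The median was -0.35 (camera adjusted p = 0.0141, and adjusted p = 0.654 with an estimated correlation). The secreted WNT antagonist genes SFRP1 (-1.13) and NOTUM (-0.57) and the inhibitor gene NKD2 (-0.89) fell and MYC (0.39) rose. The call was lost without WT replicate 2 (median -0.29, adjusted p = 0.0577) and at a minimum of 5 TPM (-0.17, 0.260), with a range of 0.00392 to 0.260. Of the interferon response genes, 8 of 19 tested members were lower and 2 higher (9 and 2 adjusted over the list alone). The median was -0.34 (camera adjusted p = 0.0223, and adjusted p = 0.465 with an estimated correlation). IFI44, the tethering factor gene BST2 (-1.25) and ISG15 (-0.79) fell and IRF9 (0.54) rose. Without WT replicate 1, 2 or 3 the median shrank to -0.14, -0.11 and -0.17 and the call was lost (adjusted p = 0.223, 0.482 and 0.379), as it was at a minimum of 5 TPM (-0.30, 0.137), with a range of 0.00620 to 0.482. Fits without 1 WT library also left out members at 1 TPM or more in WT alone, such as IFI44 and BST2. The list of replication histones and nuclear RNA had a median of -0.47 beside these falls and did not pass (camera adjusted p = 0.0686), but it passed with no filter (0.0205) and over protein-coding genes (0.00841), with a range of 0.00841 to 0.137.

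Lists that did not pass in A-KO follow with median and camera adjusted p: AMPK kinases and partners (0.17, 0.328), fatty acid oxidation (0.096, 0.663), oxidative phosphorylation (-0.10, 0.0572), mTORC1 and translation (0.065, 0.663), NRF2 antioxidant (0.12, 0.581), osteoblast lineage (0.32, 0.230), epithelial markers (-0.067, 0.663), NF-kB and inflammation (0.096, 0.921), TGF-beta response (0.16, 0.431), immediate early (0.18, 0.166), mitochondrial genome (-0.024, 0.799), cancer-testis antigens (-0.066, 0.536), housekeeping (-0.14, 0.131). Median, mean or test differed in sign for mitochondrial biogenesis (-0.0028, 0.670), p53 targets (-0.043, 0.796), YAP and TEAD targets (0.085, 0.799), extracellular matrix (0.20, 0.663), antigen presentation (-0.082, 0.166). They also differed for fatty acid synthesis (0.042, 0.663), neuronal markers (0.040, 0.921), ribosomal proteins (0.00066, 0.663), whose medians changed sign on rescaling. Ribosomal protein genes took 20.8% to 22.6% of all TPM in the A-KO libraries. Oxidative phosphorylation passed, lower in A-KO, without WT replicate 1 (0.0116) or A-KO replicate 1 (0.00653), after rescaling (0.0491) and under 3 other settings, with a range of 0.00653 to 0.318. Antigen presentation passed with no filter (0.0368) and without any one A-KO library (0.00972 to 0.0386, range over the alternatives 0.00972 to 0.325).

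**Figure D2:**
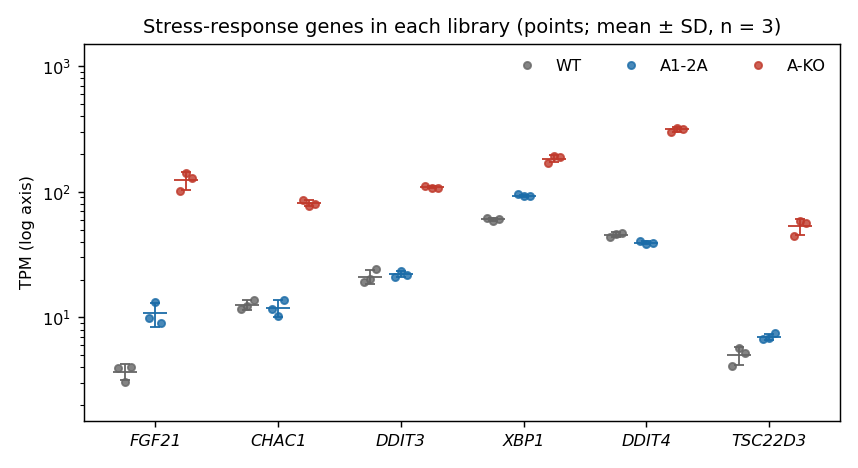
TPM (log axis) of 6 genes named for A-KO, with 1 point per library and the group mean ± SD (n = 3). FGF21 stood between 102.18 and 141.33 TPM in A-KO and between 3.07 and 13.34 TPM in WT and A1-2A, and DDIT4 between 299.97 and 324.03 TPM in A-KO and between 38.46 and 47.08 TPM in WT and A1-2A.

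Many genes differed from WT in both mutants. Over the 15068 genes tested in both comparisons, the log2 fold changes in A1-2A and A-KO correlated with r = 0.663 (Spearman's rho 0.604). This is a correlation across genes, which are not independent replicates. The sign was shared in 71.8%. Both comparisons use the same WT libraries. In 50 simulations of unchanged groups against those libraries, the mean r was 0.504 and the same-sign share 66.7%. The simulations gave 0 genes passing in both, which unchanged groups all but fix in advance, so that count is no benchmark. The covariance was 0.163, against 0.0197 (SD 0.0014) in the simulations, a difference of 0.143. In both mutants 2242 genes were higher and 1492 lower, against 1171 and 460 for independent lists, and after rescaling 1755 were higher and 2056 lower, against 761 and 841. Another 328 genes passed in opposite directions, against 1533, but 207, 167 and 191 without WT replicate 1, 2 and 3. At 2-fold, 158 genes were higher and 135 lower in both, against 13.02 and 4.61, and after rescaling 127 and 169, against 7.58 and 7.37. Both the higher and the lower overlap exceeded that of independent lists on either scale, but which was larger turned round. The 3 WT libraries are too few to give each mutant at least 2 controls of its own, and a split into 1 and 2 was not run. Part of the excess may therefore come from sharing them, such as a deviation common to all WT libraries, which the simulations do not hold.

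**Figure D3:**
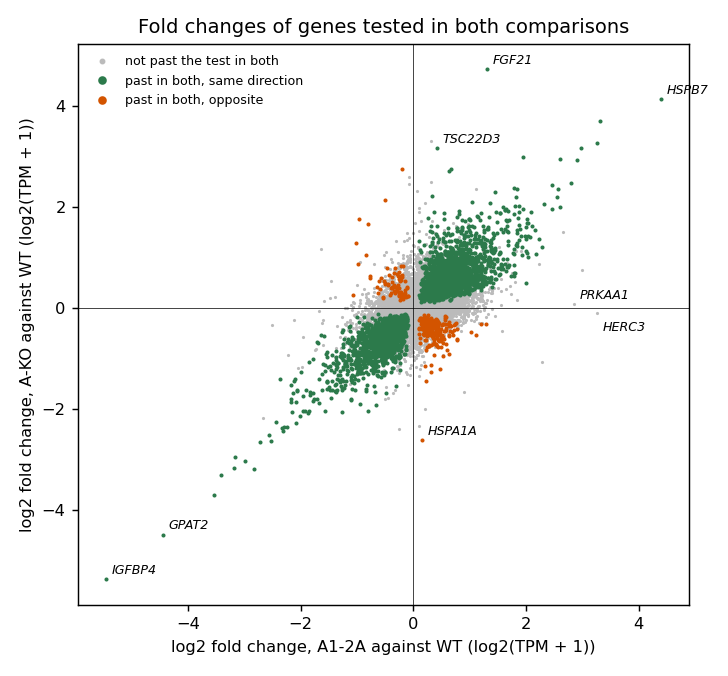
Log2 fold change of A-KO against WT (y axis) over that of A1-2A against WT (x axis), both on the log2(TPM + 1) scale, 1 point per gene tested in both. IGFBP4 and GPAT2 lie low and HSPB7 high in both, HERC3 and PRKAA1 lie to the right near 0 in A-KO, and 328 genes that passed in opposite directions lie in the upper left and lower right.

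**Figure D4:**
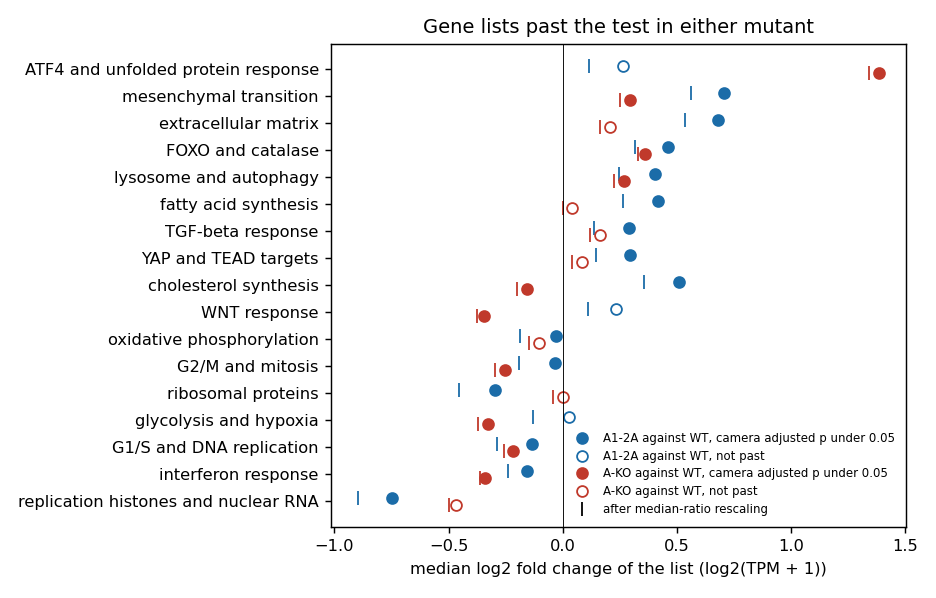
Median log2 fold change (log2(TPM + 1) scale) of each list past a camera adjusted p of 0.05 in either mutant. Filled circles passed, open circles did not, vertical ticks give the median after rescaling, and cholesterol synthesis lies at 0.51 in A1-2A and at -0.16 in A-KO.

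A1-2A was compared with A-KO directly, in a fit of all 9 libraries, which the identical WT values in the deposited tables allow. PRKAA1, HERC3, HSPA1A and HSPA1B were higher in A1-2A. The lists of cholesterol synthesis (20 of 24 higher), glycolysis (22 of 28) and matrix genes (23 of 26) stood higher, and those of ATF4 (21 of 27 lower) and ribosomal protein genes (37 of 39) lower. With an estimated correlation none of these list calls held (camera adjusted p = 0.169 to 0.243). DDIT4, a stress-induced inhibitor of mTORC1 (chromosome 10, 74033678 to 74035794), stood at 39.3 ± 1.05 TPM in A1-2A and 313 ± 12.2 in A-KO. In limma, 6240 of 16091 genes passed, 4237 higher and 2003 lower in A1-2A (67.9% higher, and 49.4% after rescaling, with 3053 and 3132). Of these, 378 differed at least 2-fold, 209 higher and 169 lower (55.3% higher, and 35.9% after rescaling, with 124 and 221). Without A-KO replicate 1, 2 or 3 the share higher at 2-fold was 43.9%, 65.3% and 59.7%, so its majority also turned on replicate 1. On data simulated for 16091 genes, the test recovered 97% of 2-fold and 68% of 1.5-fold changes, again planted outside the weaker genes.

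HERC3 (chromosome 4, 89442199 to 89629693) had the largest rise that the naming rule admits, at 43.6 ± 5.50 TPM against 3.36 ± 0.566 (log2 fold change 3.35, SE 0.19, adjusted p = 2.26e-06), followed by PRKAA1. HSPA1A (139 ± 0.516 against 19.6 ± 2.67 TPM, log2 fold change 2.77, SE 0.083, adjusted p = 6.79e-08) and HSPA1B (93.2 ± 4.66 against 16.3 ± 2.08 TPM, log2 fold change 2.45, SE 0.082, adjusted p = 1.27e-07) were both higher, and since they are near-identical the split of reads between them is uncertain. The transcript LA16c-360H6.2 stood at 9.86, 3.9 and 8.35 TPM against 1.4, 0 and 0 (2.57). FGF21 (log2 fold change -3.42, SE 0.16, adjusted p = 6.21e-07) and DDIT4 (log2 fold change -2.96, SE 0.051, adjusted p = 4.99e-10) were lower in A1-2A, as were TSC22D3 (-2.75) and CHAC1 (-2.68) and the activin subunit gene INHBE (-2.54). Among AMPK subunits PRKAB2 (0.34) was higher and PRKAB1 (-0.28) lower, the latter not without A1-2A replicate 1 (adjusted p = 0.0552) or 2 (0.0558, range 0.00440 to 0.0558). PRKAG1 (-0.23, adjusted p = 0.0710) passed only after rescaling (0.00942), without WT replicate 2 (0.0436) and under 2 other settings, with a range of 0.00942 to 0.222.

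Cholesterol synthesis parted the lines: 20 of 24 tested members were higher and 2 lower (20 and 2 adjusted over the list alone). The median was 0.75, and 0.64 after rescaling (camera adjusted p = 3.61e-09, and adjusted p = 0.169 with an estimated correlation). HMGCS1, the first committed enzyme gene of the pathway, stood at 75.3 ± 1.63 TPM in A1-2A against 27.1 ± 1.37 in A-KO (log2 fold change 1.44, SE 0.061, adjusted p = 4.00e-07), SQLE (0.99) was higher too, and PMVK (-0.41) was lower. In fatty acid synthesis, 11 of 17 tested members were higher and 0 lower (11 and 0 adjusted over the list alone). The median was 0.36, and 0.25 after rescaling (camera adjusted p = 0.00213, and adjusted p = 0.221 with an estimated correlation). The higher genes included SCD (0.89), ACLY (0.63), FASN (0.92) and FADS2 (0.51). In fatty acid oxidation, 10 of 22 tested members were lower and 3 higher (10 and 4 adjusted over the list alone). The median was -0.22, and -0.33 after rescaling (camera adjusted p = 0.00213, and adjusted p = 0.220 with an estimated correlation). The mitochondrial β-oxidation genes ACADVL (-0.48), ACAA2 (-0.53) and ECI1 (-0.61) were lower and the lipid-sensing receptor gene PPARA (0.96) higher. Among glycolysis and hypoxia genes, 22 of 28 tested members were higher and 2 lower (22 and 2 adjusted over the list alone). The median was 0.37, and 0.26 after rescaling (camera adjusted p = 1.95e-05, and adjusted p = 0.169 with an estimated correlation). PKM (0.54), HK1 (0.74) and ENO2 (0.69) were higher and VEGFA (-0.67) was lower.

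Of the ATF4 and unfolded protein response list, 21 of 27 tested members were lower and 4 higher (21 and 4 adjusted over the list alone). The median was -1.005, and -1.12 after rescaling (camera adjusted p = 5.29e-14, and adjusted p = 0.169 with an estimated correlation). ATF4 itself stood at 551 ± 9.67 TPM in A1-2A against 1124 ± 23.8 in A-KO (-1.03), DDIT3 (-2.24) was lower too, and the ER disulfide isomerase gene PDIA4 (0.56) was higher. Of the ribosomal protein genes, 37 of 39 tested members were lower and 0 higher (37 and 0 adjusted over the list alone). The median was -0.30, and -0.42 after rescaling (camera adjusted p = 1.95e-24, and adjusted p = 0.220 with an estimated correlation). Examples were RPL10A (-0.50), RPL3 (-0.45), RPSA (-0.45) and RPL13A (-0.56). The histone and nuclear RNA list moved with them, as 6 of 12 tested members were lower and 1 higher (7 and 1 adjusted over the list alone). The median was -0.50, and -0.60 after rescaling (camera adjusted p = 0.000653, and adjusted p = 0.169 with an estimated correlation). The small nucleolar RNA host gene GAS5 (-0.91) and HIST1H1C (-0.95) and HIST1H2AC (-0.68) were lower and MALAT1 (0.43) higher. Of the epithelial markers, 3 of 12 tested members were lower and 0 higher (3 and 0 adjusted over the list alone). The median was -0.25, and -0.31 after rescaling (camera adjusted p = 0.0217, and adjusted p = 0.220 with an estimated correlation). They included the claudin gene CLDN7 (-0.95) and the keratin genes KRT7 (-1.02) and KRT14 (-0.66). The call was lost without A-KO replicate 1 (median -0.23, adjusted p = 0.150) and at a minimum of 5 TPM (-0.061, 0.320), with a range of 0.00503 to 0.320. KRT14 did not pass without A1-2A replicate 2 (0.0562) or A-KO replicate 3 (0.0518, range 0.00605 to 0.0562).

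Of the extracellular matrix list, 23 of 26 tested members were higher and 1 lower (23 and 1 adjusted over the list alone). The median was 0.59, and 0.47 after rescaling (camera adjusted p = 8.45e-08, and adjusted p = 0.243 with an estimated correlation). The thrombospondin gene THBS1 (1.69), the lysyl oxidase gene LOXL2 (0.99) and SPARC (0.54) were higher and LUM (-0.78) was lower. Of the WNT response genes, 12 of 20 tested members were higher and 1 lower (13 and 1 adjusted over the list alone). The median was 0.60, and 0.51 after rescaling (camera adjusted p = 0.00185, and adjusted p = 0.304 with an estimated correlation). CCND1 (0.85), DKK3 (0.80) and FZD4 (1.20) were higher and MYC (-0.65) lower. Of the mitotic genes, 19 of 32 tested members were higher and 2 lower (19 and 4 adjusted over the list alone). The median was 0.22, and 0.11 after rescaling (camera adjusted p = 0.00134, and adjusted p = 0.304 with an estimated correlation). ANLN (0.88), KIF20A (0.77) and AURKA (0.52) were higher and CCNB2 (-0.17) lower. Of the YAP and TEAD targets, 14 of 24 tested members were higher and 2 lower (16 and 2 adjusted over the list alone). The median was 0.31, and 0.20 after rescaling (camera adjusted p = 0.0112, and adjusted p = 0.440 with an estimated correlation). TGFB2 (0.81), FJX1 (0.65) and AXL (0.59) were higher and AJUBA (-0.47) lower. Of the mesenchymal transition list, 14 of 20 tested members were higher and 1 lower (15 and 1 adjusted over the list alone). The median was 0.47, and 0.37 after rescaling (camera adjusted p = 0.00505, and adjusted p = 0.221 with an estimated correlation). CALD1 (0.71) and ITGA5 (0.52) were higher and S100A4 (-0.75) lower. At a minimum of 5 TPM, YAP and TEAD targets (adjusted p = 0.0612, range 0.000363 to 0.0612) and the mesenchymal list (0.0509, range 0.000140 to 0.0509) missed the threshold.

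Of the housekeeping genes, 12 of 23 tested members were higher and 1 lower (12 and 2 adjusted over the list alone). The median was 0.15, and 0.039 after rescaling (camera adjusted p = 0.0376, and adjusted p = 0.243 with an estimated correlation). The transferrin receptor gene TFRC (0.84), the actin gene ACTB (0.53) and VCP (0.64) were higher and PPIA (-0.12) lower. The call was lost after rescaling (adjusted p = 0.376), without A1-2A replicate 3 (0.0572) or A-KO replicate 2 (0.0572) or 3 (0.0914), and under 6 other settings, with a range of 0.000742 to 0.376. PPIA lost its call without A1-2A replicate 1 (0.0793), 2 (0.102) or 3 (0.0639), with a range of 0.00598 to 0.140. Lists that did not pass between the mutants follow with median and camera adjusted p: AMPK subunits (0.11, 0.785), AMPK kinases and partners (0.19, 0.192), lysosome and autophagy (0.15, 0.192), p53 targets (0.32, 0.0541), osteoblast lineage (0.31, 0.466), neuronal markers (0.46, 0.192), antigen presentation (0.19, 0.0533), NF-kB and inflammation (-0.099, 0.0850), TGF-beta response (0.19, 0.104), immediate early (-0.041, 0.466), mitochondrial genome (0.12, 0.598), cancer-testis antigens (0.13, 0.466). With no filter, passes were reached by AMPK kinases and partners (0.0131, range 0.0131 to 0.396), lysosome and autophagy (0.0123, range 0.0123 to 0.465) and p53 targets (0.00378, range 0.00378 to 0.163). The same held for antigen presentation (0.00709, range 0.00709 to 0.237), TGF-beta response (0.0148, range 0.0148 to 0.246) and NF-kB and inflammation (0.0462, range 0.0462 to 0.160). Median, mean or test differed in sign for mTORC1 and translation (0.20, 0.612), interferon response (0.12, 0.785). They also differed for mitochondrial biogenesis (0.021, 0.565), oxidative phosphorylation (0.0016, 0.466), NRF2 antioxidant (0.098, 0.937), FOXO and catalase (0.050, 0.247), G1/S and DNA replication (0.00050, 0.192), whose medians changed sign on rescaling.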

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

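Chosen only after the results were seen were the tests of a shift of all genes alike, of shared WT libraries, of bins against shuffled bins and of a single A-KO library, and the counts over other splits. Results stood out here where the mutants differed from each other in a direct test, and groups of 3 libraries were not tested for outlying samples. Cholesterol synthesis stood out because the median of the list was positive in A1-2A (0.51) and negative in A-KO (-0.16) against WT, and the direct comparison of the mutants gave a median of 0.75. In A-KO 9 of 24 members were lower and 13 did not pass, and with an estimated correlation the camera calls were lost (adjusted p = 0.400 in A1-2A, 0.530 in A-KO and 0.169 directly). Another 328 genes stood out because they passed in opposite directions in the mutants, against 1533 for independent lists. The count fell to 207, 167 and 191 without WT replicate 1, 2 and 3, to 187 with the replicate number as a block and to 194 with no filter. All 328 also differed between the mutants directly, which opposite differences from the same WT libraries all but require. Of these, 248 were higher in A1-2A and lower in A-KO, and 80 the other way.

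In A1-2A, 35 of 39 ribosomal protein genes were lower and 2 higher. The camera call of this list was lost with an estimated correlation (camera adjusted p = 0.400). After removing the trend of other genes with transcript length and GC content, the median of the list was -0.34. It ran from -0.39 to -0.31 without any one library. Length and GC content were those of the longest transcript of each gene, which need not be the one expressed. A bias by either therefore stays open for this list. A shift of all genes by the fixed TPM total is argued against because the list lay -0.43 from the median of all genes. This restates the median of -0.45 after rescaling and is no separate evidence. A changed growth state, a clonal difference of the line and the A1-2A genotype stay open and were not tested, since each goes with the group. RNA quality or selection in library making stays open as well, as the histone and nuclear RNA list was lower in the same libraries. The lists did not fall together in A-KO against WT. There the histone and nuclear RNA median was -0.47 (camera adjusted p = 0.0686) and the ribosomal protein median 0.00066 (0.663).

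Changes shared by A1-2A and A-KO gave a covariance of 0.163, far above the 0.0197 (SD 0.0014) simulated for shared WT libraries. That argues against scatter between the shared WT libraries as the whole cause. A deviation common to all WT libraries is not in the simulation, so it stays open. Of the covariance, 20.1% lay between 10 Mb bins (20.1% to 21.8% without any one library, over 13444 genes in 249 bins). That argues against blocks of changed chromosomal dosage on the scale of these bins as the main source of the covariance. The covariance weighs large changes most, and blocks smaller than a bin or crossing bins fall partly within them. The share therefore does not tell how many of the shared genes lie in such blocks. For part of the changes such blocks may hold, because shuffled bins gave a mean of 1.85% and at most 2.68% (one-sided permutation p = 0.001, the smallest that 1000 shuffles can give). Examples chosen after their values were seen are 30 to 40 Mb of chromosome 6 (54 genes, medians 0.63 in A1-2A and 0.61 in A-KO) and 0 to 10 Mb of chromosome 7 (79 genes, -0.46 and -0.50). The bins do not tell whether such blocks arose in WT or in both mutants. Drift or clonal origin of the edited lines and an effect of altered AMPK in both go with the groups. Beyond the bins neither was tested, and both stay open.

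In A-KO, 21 of 27 members of the ATF4 and unfolded protein response list were higher and 0 lower. The camera call of this list was lost with an estimated correlation (camera adjusted p = 0.465). A single deviating A-KO library is argued against, since the list's median stayed at 1.26 or above without any one of them. After removing the trend with length and GC content of the longest transcripts, the median was 1.30. The expressed transcript may be another one, so a bias by either is not settled by this value. Loss of AMPKα, a clonal difference and nutrient or culture state at harvest go with the group and stay open, untested.

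Other splits of the 6 libraries of a comparison into groups of 3 number 10 with the real one, too few for a share under 0.05, and in each comparison 1 of 10 splits, the real one, gave a count as large. Every other split mixes libraries of both lines in each group, so the difference between the lines enters the spread. Low gene counts there are built in, and no conclusion is drawn from them. The real split gave 8286 genes (761 at 2-fold) for A1-2A against WT, and the highest other split 1 (1). It gave 6025 (737) for A-KO against WT, and the highest other 0 (0). For A1-2A against A-KO it gave 6240 (378), and the highest other 3 (3). Gene lists numbered 14, 10 and 14 in the real splits and 9, 8 and 9 in the highest others.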

How the results depend on the processing

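The alternatives with protein-coding genes only and without mitochondrial and ribosomal protein genes were chosen after seeing the data. A result was counted as kept if it stayed on its side of the threshold. Changes of sign were counted only where the main or the alternative fit passed. Medians that turned sign without passing are therefore among those kept. Leaving out 1 replicate kept 191 of 198 list results for A1-2A against WT. It kept 189 of 198 for A-KO against WT and 290 of 297 for A1-2A against A-KO. Other settings kept 308 of 328, 318 of 327 and 312 of 328. For named genes, 442 of 444, 343 of 345 and 613 of 621 were kept without 1 replicate. Under other settings 772 of 780, 626 of 626 and 672 of 679 were kept. These totals count only fits in which the gene met the minimum. Among the largest changes against WT, IGFBP4, GPAT2, ANXA10, IFI44 and HOXB2 were not tested without any one WT library. HSPB7 was not tested without any one library of the mutant. Reversals so counted were 3, all of list medians for A1-2A against WT. Leaving out single libraries moved the median of G2/M and mitosis from -0.077 (without WT replicate 3) to 0.030 (without WT replicate 1), and of interferon response from -0.19 (without A1-2A replicate 2) to 0.044 (without WT replicate 3). Without WT replicate 2 the interferon median was 0.042. Fits without 1 WT library also left out interferon genes at 1 TPM or more in WT alone, such as IFI44. How far that moved the median was not tested, nor was the cause for the mitotic list.

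Counts at 2-fold depended on the scale. A pseudocount of 0.1 gave 1338, 1250 and 781 genes for A1-2A against WT, A-KO against WT and A1-2A against A-KO, because it shrinks low genes less. Testing against a 2-fold null with treat gave 135, 125 and 34, because the null is stricter. A minimum of 5 TPM gave 490 for A-KO against WT, with fewer genes tested. With an estimated correlation camera passed 0, 0 and 0 lists, beside 3, 3 and 7 at an unadjusted p under 0.05, while fry, which does not compare a list with other genes, passed 27, 20 and 26. The cause of the loss with estimated correlations was not tested. The correlation of the mutants' fold changes was 0.663 (jackknife SE 0.0275), 0.691 at a minimum of 5 TPM, 0.693 over protein-coding genes, and 0.632 (without A-KO replicate 2) to 0.666 (without WT replicate 1) when libraries were left out. With the replicate number as a block, 7787, 4724 and 5418 genes passed, 768, 740 and 378 at 2-fold, and 12, 10 and 13 lists. Libraries of the same number showed no sign of pairing, since after group means were removed their correlations ran from -0.14 to 0.0038, and libraries of other numbers correlated as high as 0.16. Antigen presentation, not past the threshold in any comparison, passed in A-KO without A-KO replicate 1, 2 or 3 (adjusted p = 0.00972, 0.0386 and 0.0330, range over the alternatives 0.00972 to 0.325), and between the mutants without A1-2A replicate 1 or 3 or A-KO replicate 1 (0.0327, 0.0395 and 0.0169, range 0.00709 to 0.237). TPM keeps no depth, so what depth limits could not be computed, and changes of low genes are understated by the pseudocount of 1.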

Other observations

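The test of ATF4 targets against ER chaperones was chosen only after the result was seen, and the test of other HSF1 targets was fixed before its result was seen. The fall of HSP70 genes in A-KO raised the hypothesis that heat shock factor HSF1 may have been less active there. The median of 13 other HSF1 targets was -0.80 in A-KO against WT, with 12 of 13 lower (camera p = 3.98e-11 on limma values, and p = 0.00589 with an estimated correlation), and 13 of 13 were higher in A1-2A than in A-KO. In A1-2A against WT their median was 0.068, with 4 higher and 1 lower. The same A-KO libraries enter both comparisons with A-KO, so the second is no independent support. These camera p-values were not adjusted over lists. Lower HSF1 activity is a candidate explanation, and the data do not say whether it goes with the loss of AMPKα, the clone or the culture.

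The rise of ATF4 targets in A-KO raised the question whether it came with a general response to unfolded proteins. The median of 18 ATF4 targets was 1.58 and that of 8 ER chaperone and folding genes 0.17, a difference of 1.42. The rise of the ATF4 targets had a camera p = 3.66e-13 on limma values, and p = 0.0533 with an estimated correlation. An exact permutation of list membership over 1562275 arrangements gave a two-sided p of 0.00109, but it was run on the genes whose separation prompted it and adds no evidence of its own. Of the ER genes, 4 of 8 were higher in A-KO and 0 lower (camera p = 0.0175 on limma values, and p = 0.123 with an estimated correlation). In A1-2A, 8 of 8 were higher (median 0.44, camera p = 0.000697 on limma values, and p = 0.103 with an estimated correlation) while the ATF4 targets had a median of 0.10. Between the mutants the ER genes had a median of 0.13 (camera p = 0.838 on limma values, and p = 0.863 with an estimated correlation). What raised either group was not tested, and whether the ATF4 targets rose without a response to unfolded proteins stays open.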
